A study of Homo sapiens with 15 samples.

How the data were processed

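Nuclease-accessible chromatin was measured in 15 libraries of K562 cells, 3 in each of 5 groups, and each library came as one list of peaks in narrowPeak layout on the human genome build hg19. Per the submitters' processing notes, reads were processed with CASAVA 1.3 and aligned to hg19 with BWA, and bedtools was used; the peak caller, its threshold and the total number of fragments are not given in the sources used here. Peak names begin with the prefix that MACS writes, and the columns were read in narrowPeak order. The fold column, a ratio, is the authors' own value for each peak, the enrichment at the summit over the local background of that library. It was used to rank and describe peaks within a list. Together with the p-value column it also gave the implied summit pileup, which was compared between libraries. The p-value and q-value columns were deposited as −log10 of each peak's p-value and q-value. The score column was deposited as a whole number and equals 10 times the −log10 q-value without its decimals in at least 99.995% of the peaks of each list. No normalization between libraries is recorded in the labels.

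Samples were grouped by their titles and the design text: dCas9-KRAB without a gRNA, dCas9 with Cr4, dCas9 with Cr10, dCas9-KRAB with Cr4 and dCas9-KRAB with Cr10. The groups, the comparisons, the tests, the 11 windows of the beta-globin cluster and the alternatives were fixed before the data were examined, except those marked in the text as chosen later. The windows that carry the names HS1 to HS5, 3′ HS1 and the globin promoters use recalled hg19 positions, not checked against an annotation. The comparisons were each gRNA under dCas9-KRAB and under dCas9 against dCas9-KRAB without a gRNA, dCas9-KRAB against dCas9 for each gRNA, Cr4 against Cr10 under dCas9-KRAB, and the 6 libraries with dCas9-KRAB and a gRNA pooled against the other 9. Named in the text, by a rule fixed in advance, are HS2, every fixed site of the beta-globin cluster and the genes with homology to the vector, plus up to 10 regions in each direction past the threshold in each comparison. Some loci covered by these lists are not reported here. Regions named outside this rule are marked as chosen after their values were seen.

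Peaks on the autosomes and X were ranked by fold within each list, and each list was shortened to 53098 peaks, the length of the shortest. This kept between 56.1% and 100% of the peaks of a library. Kept peaks that overlapped by at least 1 bp were merged into 78357 regions, of which the 62855 with a peak in at least 3 libraries were tested. A region's value in a library was the rank percentile of its strongest peak, 100 for the strongest peak and 0 for no peak. Limma fitted all 15 libraries and 5 groups at once with a mean-variance trend, and p-values, all two-sided, were adjusted by Benjamini and Hochberg with a threshold of 0.05, over all regions and, for the globin sites, over the list alone. HS2 itself was tested by exact permutation of the difference of means and by Fisher's exact test for presence. The similarity of lists was tested by permuting group labels in 100000 draws.

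The implied summit pileup was computed after the ranks had been seen. MACS-type peaks hold fold = (k + 1)/(λ + 1), with k the pileup at the summit and λ the local background, and a Poisson p-value of k given λ. For every peak of all 15 lists a whole number k met both columns within 0.01 in −log10 p, against 4.2% to 6.0% of peaks when p-values were moved at random. The measure tested was log2(k + 1) less the median of the library over the 38888 regions with a peak in all 15 deposited lists. It was fitted by limma in the same way.

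The limma script was tested on simulated data made from these lists, with 50 changed regions at each of 4 sizes. The simulated noise was drawn independently for each library, without the structure that the real libraries share, so the shares called may not hold for the real lists. In the pooled comparison it called 14%, 54%, 80% and 54% of regions with median differences of −15.6, −24.8, −51.0 and 24.4 percentile points, and 16 of 62655 unchanged regions. In dCas9-KRAB with Cr10 against no gRNA it called 0%, 24%, 58% and 14% at −14.5, −26.6, −52.3 and 24.5 points, and 9 unchanged regions. On the pileup the pooled comparison called 34%, 84%, 96% and 92% of regions changed by −0.40, −0.70, −1.10 and 0.70 in log2, and 2 of 38688 unchanged regions. In dCas9-KRAB with Cr10 against no gRNA the pileup fit called 2%, 30%, 78% and 46% at these sizes, and 3 unchanged regions.

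Alternatives covered the 50000 strongest peaks, percentiles in the deposited lists, the log2 of the rank, other filters and overlaps, the limma settings, the replicate number as a block, and leaving out each library. The tests of gene lists at promoters were not run because they need gene positions on hg19, which were not used here, and regions were not assigned to nearby genes. Analyses ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.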

Results

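Open chromatin was mapped in K562, a human erythroleukemia cell line that transcribes the embryonic and fetal globin genes, after lentiviral delivery of a catalytically dead Cas9 (dCas9) that binds DNA through a guide RNA (gRNA) without cleaving it. In part of the cultures dCas9 was fused to the KRAB domain, a repressor domain of zinc finger proteins that recruits co-repressors and histone methyltransferases. The gRNAs were aimed at HS2, a DNase I hypersensitive site and strong erythroid enhancer in the locus control region upstream of HBE1, the embryonic member of the beta-globin cluster. The 15 libraries formed 5 groups of 3: dCas9-KRAB without a gRNA, dCas9 with gRNA Cr4, dCas9 with gRNA Cr10, dCas9-KRAB with Cr4 and dCas9-KRAB with Cr10. One annotation field named HS2 as the gRNA target in the group without a gRNA as well, so the groups followed the sample titles and the design text. The series description states transductions in triplicate; where nothing says that the numbered libraries came from separate cultures, the p-values measure only the spread between these samples, which may be technical.

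Each library was represented by its own list of peaks, that is, of regions where nuclease-cut fragments piled up above the local background. The lists held from 53147 peaks (dCas9 with Cr10, replicate 1) to 94777 peaks (dCas9 with Cr10, replicate 3). The mean length was 70943 ± 15135 peaks (SD, n = 3) with dCas9-KRAB alone, 75387 ± 10063 with dCas9 and Cr4, 71755 ± 21163 with dCas9 and Cr10, 72576 ± 14276 with dCas9-KRAB and Cr4, and 66131 ± 4994 with dCas9-KRAB and Cr10. Lists of different length thus occurred within groups as well as between them. The total number of sequenced fragments was not given in the sources used here. A stand-in for depth, the pileup implied for the quietest backgrounds, ran from 2.21 to 5.81 fragments over the 15 libraries. After every list was shortened to its 53098 strongest peaks on the autosomes and X, the peaks merged into 78357 regions, of which 34009 had a peak in all 15 libraries.

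**Figure D1:**
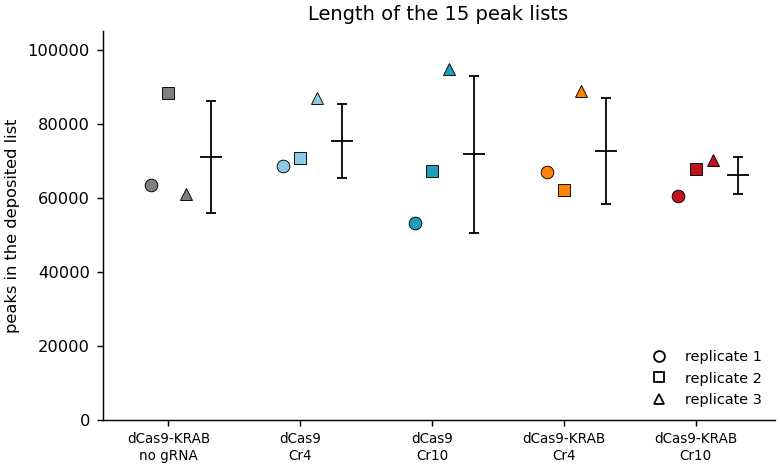
Number of peaks in each of the 15 deposited lists (vertical axis), by group (horizontal axis); symbols mark the replicate number, and the black bar and whiskers give the mean and SD of the 3 libraries. The lists run from 53147 to 94777 peaks, and both ends lie in the group with dCas9 and Cr10.

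The first question was whether the HS2 peak was lost where dCas9-KRAB was brought to it. It was not lost: all 15 deposited lists held a peak at HS2 (hg19, chromosome 11, 5301766 to 5302230 over all libraries), including the 6 libraries with dCas9-KRAB and a gRNA. Presence was also complete in the lists of equal length. Among the strongest 50000 peaks of each list it was present in 5 of 6 libraries with dCas9-KRAB and a gRNA and in 9 of 9 others, and the library without it was replicate 2 of dCas9-KRAB with Cr10 (Fisher's exact test, two-sided, p = 0.4).

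The HS2 peak was weaker where dCas9-KRAB was directed to it. Its rank percentile, where 100 is the strongest peak of a library and 0 stands for no peak in the equal-length list, averaged 41.7 ± 25.8 (SD, n = 6) with dCas9-KRAB and a gRNA and 63.8 ± 13.5 (n = 9) in the other libraries. The difference of −22.1 percentile points passed the two-sided exact permutation test fixed for HS2 before the data were examined (p = 0.0432, 5005 splits). The low values came mainly from Cr10. In dCas9-KRAB with Cr10 the 3 libraries stood at 50.6, 1.94 and 19.0, whereas the 3 libraries with dCas9-KRAB and Cr4 stood at 65.9, 48.0 and 64.6. The call was fragile. Without replicate 2 of dCas9-KRAB with Cr10 the difference was −14.1 (exact permutation p = 0.129), and without its replicate 3 it was −17.6 (p = 0.108). It also missed the threshold, by exact permutation, without replicate 2 of dCas9-KRAB with Cr4 (−23.4, p = 0.0504), replicate 1 of dCas9 with Cr4 (−20.7, p = 0.0739), replicate 1 or 2 of dCas9 with Cr10 (−21.4, p = 0.0669, and −19.5, p = 0.0756), replicate 1 or 3 without a gRNA (−21.3, p = 0.0686, and −21.0, p = 0.0713), and on the log2 of the rank (−0.67, p = 0.0525).

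**Figure D2:**
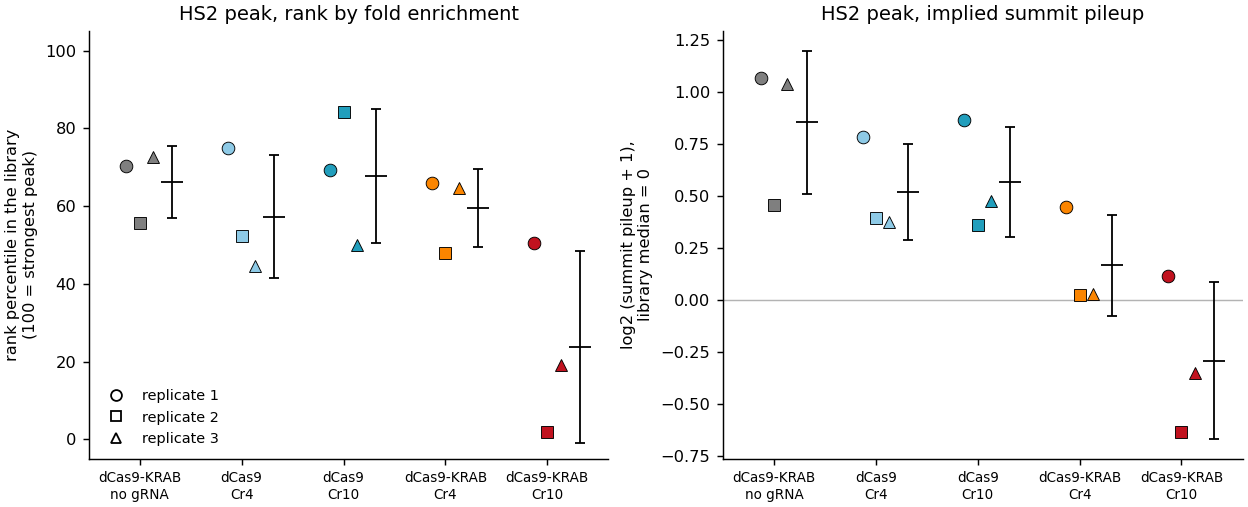
HS2 peak in each library by group. Left, rank percentile (100 is the strongest peak); right, log2 of the implied summit pileup plus 1, with the library's median over common peaks at 0. Symbols mark replicate numbers, and black bars and whiskers give mean and SD (n = 3). The 3 libraries with dCas9-KRAB and Cr10 have the lowest group mean in both panels, 23.8 and −0.29.

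With gRNA Cr10, dCas9-KRAB lowered HS2 against both kinds of control. The mean percentile was 23.8 ± 24.7 (SD, n = 3), against 66.2 ± 9.19 with dCas9-KRAB and no gRNA and 67.8 ± 17.2 with dCas9 and Cr10. The differences were −42.3 and −43.9 points. Limma's adjusted p at HS2 was 0.0274 and 0.0209, adjusted over the list alone of 9 globin sites fixed beforehand, and 1.00 over all 62855 regions in both. Each of the 3 libraries with dCas9-KRAB and Cr10 lay below all 3 libraries without a gRNA. Against dCas9 with Cr10 the groups overlapped, with the highest dCas9-KRAB library at 50.6 and the lowest dCas9 library at 49.9. In exact permutation tests p was 0.1 and 0.2, and 3 libraries against 3 cannot go below 0.1. Both limma calls depended on single libraries: without replicate 2 or 3 of dCas9-KRAB with Cr10 the differences were −31.4 and −39.9 against no gRNA (adjusted p over the list alone 0.168 and 0.1003) and −33.0 and −41.5 against dCas9 with Cr10 (0.144 and 0.0795). They were −40.3 and −39.2 without replicate 1 or 3 of the no-gRNA group (limma adjusted p 0.109 and 0.0911), and −43.2 and −35.7 without replicate 1 or 2 of dCas9 with Cr10 (0.0741 and 0.157).

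With gRNA Cr4, the rank of HS2 did not pass a test against either control, while its summit pileup was lower than without a gRNA. The mean percentile was 59.5 ± 10.0 (SD, n = 3) with dCas9-KRAB and 57.3 ± 15.7 with dCas9. The difference from dCas9-KRAB without a gRNA was −6.71 points (exact permutation p = 0.5), and that from dCas9 with Cr4 was 2.18 points (exact permutation p = 0.9). The direct comparison of the gRNAs under dCas9-KRAB gave a percentile 35.6 points higher with Cr4 than with Cr10 (exact permutation p = 0.2; limma's adjusted p over the list alone 0.0870). On the implied summit pileup, chosen after the ranks had been seen, HS2 with dCas9-KRAB and Cr4 differed by −0.69 in log2 (0.620 times) from no gRNA and by −0.35 from dCas9 with Cr4 (limma adjusted p over the list alone 0.00573 and 0.168, over all regions 1.00 in both; exact permutation p = 0.1 and 0.3).

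With dCas9 that lacked the repressor domain, HS2 did not pass a test against dCas9-KRAB without a gRNA. By rank the difference was −8.89 points with Cr4 (exact permutation p = 0.5) and 1.59 points with Cr10 (exact permutation p = 1). On the implied summit pileup, a measure chosen after the ranks had been seen, the log2 differences were −0.34 with Cr4 and −0.29 with Cr10 (SE 0.19 each; limma adjusted p over the list alone 0.631 and 0.489). Both comparisons change the gRNA and the KRAB domain at once, and no group had dCas9 without a gRNA.

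Across the beta-globin cluster, 4 of the 9 fixed sites with a tested region differed by rank between the 6 libraries with dCas9-KRAB and a gRNA and the other 9, and 0 of them did so over all regions. HS2 (−22.1 points, SE 7.81) and HS3, the neighbouring enhancer of the locus control region (5305792 to 5306310; −16.3, SE 6.33), ranked lower. HS1 (5296783 to 5297378; 25.1, SE 8.14) and HS4 (5309327 to 5309737; 15.9, SE 6.20) ranked higher. The limma adjusted p was 0.0471 for each of the 4, adjusted over the list alone, and 1.00 over all 62855 regions. The promoters of the fetal genes HBG2 (5275738 to 5276312; −9.87, SE 5.38) and HBG1 (5270839 to 5271354; −8.55, SE 4.65) had an adjusted p of 0.129; these genes are near-identical copies, so the assignment of fragments between them is uncertain. HS5 (5312466 to 5312801; −2.91, SE 6.68), 3′ HS1 (5226033 to 5226442; 0.548, SE 3.27) and the promoter of the adult gene HBD (5255349 to 5256040; 0.785, SE 2.95) did not pass. The window at the HBE1 promoter had a peak in 4 deposited lists, none of them with dCas9-KRAB and a gRNA. These peaks had implied summit pileups of 21 to 52, and in the equal-length lists only the group with dCas9 and Cr10 kept one. A loss at HBE1 with dCas9-KRAB and a gRNA is therefore not shown. The window at HBB, the adult beta-globin gene, had a peak in 0 lists. The count of 4 sites that differed by rank was not stable, since it was 0 without any one of 10 libraries (all but those in the next sentence). It was 1 without replicate 3 of the no-gRNA group, 2 without replicate 3 of dCas9 with Cr10 or replicate 1 of dCas9-KRAB with Cr10, 3 without replicate 1 of dCas9-KRAB with Cr4, and 4 without replicate 3 of dCas9 with Cr4.

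**Figure D3:**
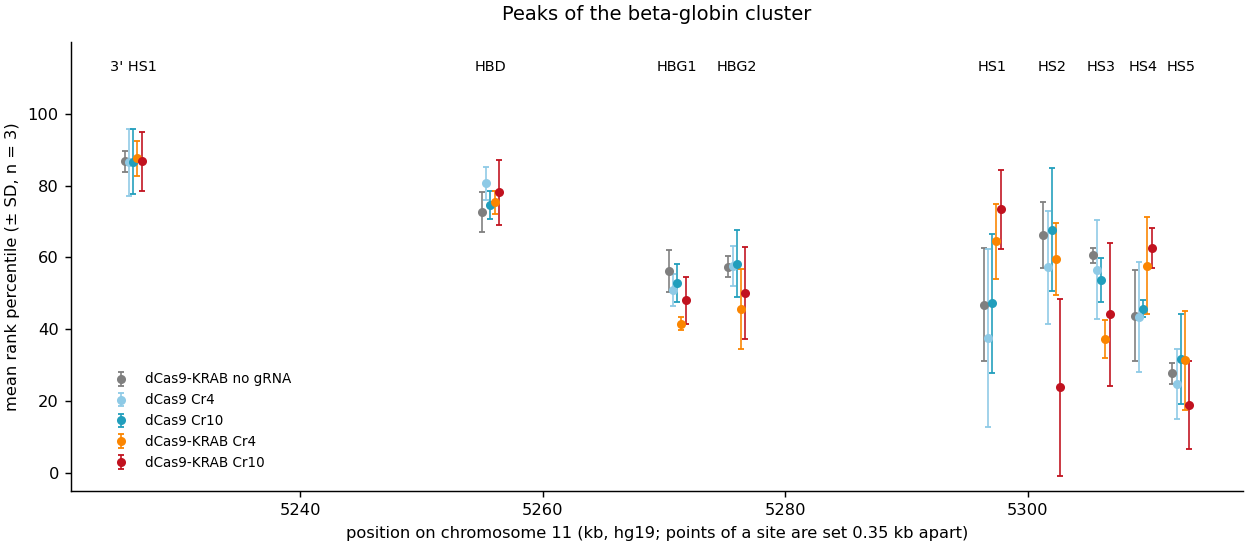
Beta-globin cluster on chromosome 11 (hg19, horizontal axis in kb) with the mean rank percentile of each site (vertical axis) in the 5 groups; whiskers give the SD of 3 libraries. HS2 in dCas9-KRAB with Cr10 has the lowest mean of the groups at that site, 23.8.

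In single comparisons of 3 libraries against 3, HS2 was the 1 globin site past limma's threshold over the list alone in dCas9-KRAB with Cr10 against no gRNA and against dCas9 with Cr10. In the other 5 comparisons limma called 0 of 9 sites over the list alone, with 1, 0, 0, 1 and 1 sites at an unadjusted p under 0.05 for dCas9-KRAB with Cr4 against no gRNA, dCas9 with Cr4 against no gRNA, dCas9 with Cr10 against no gRNA, dCas9-KRAB with Cr4 against dCas9 with Cr4, and Cr4 against Cr10 under dCas9-KRAB. At HS3, dCas9-KRAB with Cr4 lay at 37.1 ± 5.30 (SD, n = 3), below 60.6 ± 2.08 without a gRNA, a difference of −23.4 points (exact permutation p = 0.1, limma's adjusted p over the list alone 0.258). A second measure, the fragment pileup at the summit implied by the fold and p columns, was chosen after the ranks had been seen. On it HS2 (log2 difference −0.71, SE 0.12) and HS3 (−0.52, SE 0.13) were lower in the 6 libraries with dCas9-KRAB and a gRNA, with limma adjusted p of 4.34e-05 and 0.00272 over the list alone and 0.187 and 1.00 over 38888 regions. HS1 and HS4 differed by 0.12 each (SE 0.16 and 0.15, adjusted p over the list alone 0.654), while the local background was lower at HS1 by −0.34 (two-sided exact permutation p = 0.0190).

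**Figure D4:**
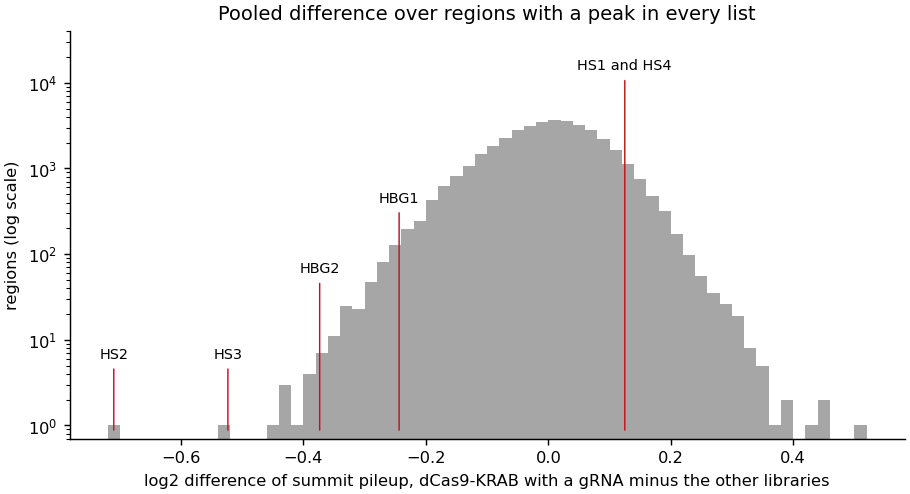
Histogram of the log2 difference in implied summit pileup (horizontal axis) between the 6 libraries with dCas9-KRAB and a gRNA and the other 9, over 38888 regions with a peak in every deposited list; the vertical axis counts regions on a log scale and red lines mark globin sites. HS2 at −0.71 and HS3 at −0.52 are the lowest of all regions.

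Beyond the globin cluster, the comparisons asked for off-target changes in open chromatin. By rank, limma called 0 of 62855 regions in each of the 8 comparisons at an adjusted p of 0.05. The counts at an unadjusted p under 0.05 were 1522 for dCas9-KRAB with Cr4 against no gRNA, 1764 for dCas9-KRAB with Cr10 against no gRNA, 871 and 1872 for dCas9 with Cr4 and with Cr10 against no gRNA, 785 and 1569 for dCas9-KRAB against dCas9 with Cr4 and with Cr10, 1664 for Cr4 against Cr10 under dCas9-KRAB, and 1083 for the pooled comparison. On the summit pileup limma also called 0 of 38888 regions in each, with 281, 327, 121, 423, 82, 504, 279 and 299 regions at an unadjusted p under 0.05 in the same order. On both measures every count was a smaller share of the tested regions than the 0.05 that no change would give. These counts are therefore no sign of change. The p-values may also be too large here, so the 0 calls do not exclude changes. On simulated lists, shifts with a median of −24.8 percentile points were called in 54% of changed regions in the pooled comparison, and shifts with a median of −26.6 points in 24% in dCas9-KRAB with Cr10 against no gRNA, so changes of that size at single regions could be missed. The simulated noise was independent between libraries, so these shares may not hold for the real lists. HS2 was 144th of 62855 regions by limma p in the pooled comparison, 63rd in dCas9-KRAB with Cr10 against no gRNA and 31st in dCas9-KRAB with Cr10 against dCas9 with Cr10. The lowest p of the pooled comparison belonged to a region on chromosome 6 (123190648 to 123190889; −13.1 points, SE 3.12), followed by a region on chromosome 14 (91124835 to 91125466; −19.1, SE 4.62) and a region of the beta-globin cluster (chromosome 11, 5279809 to 5280193; −15.5, SE 3.81), all chosen after their values were seen and all with a limma adjusted p of 1.00. Leaving out replicate 3 of dCas9 with Cr10 raised the count to 1 against no gRNA (chromosome 22, 37484189 to 37484454, 39.8 points higher in dCas9 with Cr10) and to 2 in dCas9-KRAB with Cr10 against dCas9 with Cr10 (that region, −38.2, and chromosome 1, 162246350 to 162246618, −33.9). Leaving out replicate 3 of dCas9-KRAB with Cr10 gave 1 region (chromosome 18, 20633853 to 20634263) in each of the 3 comparisons with that group, 35.2 points higher with dCas9-KRAB and Cr10.

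Peaks gained or lost outright were few. Of 120992 regions merged from the deposited lists, 0 had a peak in all 6 libraries with dCas9-KRAB and a gRNA and in none of the other 9, or the reverse. Fisher's exact test with Benjamini-Hochberg adjustment called 0 of 82104 regions, with 469 at an unadjusted p under 0.05. With 6 against 9 libraries, even a perfect split of a single region gives a Fisher p too large to pass over that many tests. The 0 calls of that test therefore say little about single regions. For 3 against 3, regions with a peak in all libraries of one group and none of the other numbered 111 gained and 76 lost in dCas9-KRAB with Cr4 against no gRNA, and 71 gained and 262 lost in dCas9-KRAB with Cr10 against no gRNA. They numbered 20 gained and 38 lost in dCas9 with Cr4, and 47 gained and 49 lost in dCas9 with Cr10, against no gRNA. Under dCas9-KRAB rather than dCas9, 11 were gained and 181 lost with Cr4, and 7 were gained and 185 lost with Cr10. Cr4 against Cr10 under dCas9-KRAB gave 360 and 41. In lists of equal length the gained and lost regions numbered 144 and 137 for dCas9-KRAB with Cr4, 122 and 144 for dCas9-KRAB with Cr10, and 74 and 62 for dCas9 with Cr4 against no gRNA, and for dCas9 with Cr10 against no gRNA 122 of 223 were lost. They numbered 78 and 93 for dCas9-KRAB against dCas9 with Cr4, 67 and 87 with Cr10, and 169 and 125 for Cr4 against Cr10. The counts from the deposited lists were not larger than regroupings of the same libraries gave: the medians over the other 9 splits were 389, 673, 659, 299, 681, 717 and 748 regions, against real totals of 187, 333, 58, 96, 192, 192 and 401 in the order of this paragraph. Leaving out any 1 of the 6 libraries of a comparison raised each total by more than 1.5 times, to between 221 and 2306 regions. The pooled count of 0 became 4 without replicate 3 of dCas9-KRAB with Cr4 and 1 without replicate 1 of dCas9 with Cr10.

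Libraries of one group did not resemble each other more than libraries of other groups. The mean Jaccard index, the bases shared between a pair of equal-length lists over the bases covered by either, was 0.687 over 15 pairs within groups and 0.704 over 90 pairs between groups. The difference of −0.0165 gave p = 0.998 in a one-sided permutation test with 100000 draws, so pairs within groups shared fewer bases than pairs between groups. Pairs within a group never had the same replicate number, while 30 of the 90 pairs between groups did. Lists of the same number shared more bases (Jaccard index 0.713 against 0.697), which could have lowered the difference. Over all pairs the index ran from 0.608 to 0.804. The closest pair, replicate 2 without a gRNA and replicate 2 of dCas9 with Cr4, shared 0.804 of their bases, so that no library was a copy of another.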

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

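The difference between the gRNAs below was chosen for testing after the HS2 values had been seen. At HS2 the change from dCas9 to dCas9-KRAB differed between Cr10 and Cr4 by −46.1 percentile points (SE 17.1), with a two-sided limma p of 0.0162, and 0.145 when adjusted over the list alone of 9 globin sites. On the implied summit pileup the same difference was −0.51 in log2 (SE 0.27, limma adjusted p over the list alone 0.641).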

How the results depend on the processing

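The alternatives on the summit pileup and those for the similarity of lists without single libraries were chosen after seeing the data, and all others before. Over 54 results, 552 of 730 alternatives were scored as unchanged. For differences this meant the same direction and side of the threshold. For counts of regions or sites it meant only an equal or similar count. The total therefore mixes different rules. It also includes HS2 presence, which could hardly change because every deposited list held that peak. HS2 presence and the similarity of lists within groups (−0.0201 to −0.0112 without single libraries) were scored as unchanged throughout. So was the summit pileup of HS2 (log2 difference −0.81 to −0.60 without single libraries, exact permutation p between 0.000500 and 0.00500). Depth is known only through the implied background, and regions without a called peak have no value, so weak changes near the limit of the peak calls are not resolved. Leaving out 1 library leaves 2 against 3 and relies on the spread of the other groups. The alternatives for gene lists at promoters (5 kb and the block) were not run.

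With percentiles in the deposited lists, HS2 in dCas9-KRAB with Cr4 against dCas9 with Cr4 was −1.26, and the globin sites past the threshold over the list alone numbered 1 in Cr4 against Cr10 and 1 in the pooled comparison. On the log2 of the rank, pooled HS2 was −0.67 (exact permutation p = 0.0525). With equal-length lists, regions gained or lost numbered 281, 136 and 223 for dCas9-KRAB with Cr4, dCas9 with Cr4 and dCas9 with Cr10 against no gRNA. On the summit pileup, the globin sites past the threshold over the list alone numbered 4 for dCas9-KRAB with Cr4 and 2 for dCas9-KRAB with Cr10 against no gRNA, and 3′ HS1 was −0.0202 in the pooled comparison. The cause of these changes was not tested.

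Without single libraries, HS2 by rank ran from −26.9 to −14.1 in the pooled comparison, from −6.63 to 10.5 in dCas9 with Cr10 against no gRNA and from −4.17 to 10.99 in dCas9-KRAB against dCas9 with Cr4. Regions past the limma threshold ran from 0 to 1 for dCas9-KRAB with Cr10 and for dCas9 with Cr10 against no gRNA, from 0 to 2 for dCas9-KRAB with Cr10 against dCas9 with Cr10, and from 0 to 1 for Cr4 against Cr10. Regions gained or lost ran from 664 to 1408 (dCas9-KRAB with Cr4), 844 to 1614 (dCas9-KRAB with Cr10), 221 to 2232 (dCas9 with Cr4) and 363 to 1329 (dCas9 with Cr10) against no gRNA, from 368 to 1608 (Cr4) and 341 to 2306 (Cr10) for dCas9-KRAB against dCas9, from 1043 to 1980 for Cr4 against Cr10, and from 0 to 4 in the pooled comparison. With fewer libraries fewer lists must share or lack a peak, which raises these counts by construction. Globin sites past the threshold ran from 0 to 1 for dCas9-KRAB with Cr10 against no gRNA and against dCas9 with Cr10 and for Cr4 against Cr10, and from 0 to 4 in the pooled comparison. HS5 ran from −6.45 to 0.998, 3′ HS1 from −1.07 to 2.86 and the HBD promoter from −1.81 to 2.50. The cause was not tested.

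The replicate number was also taken as a block, although the samples share only a number. Correlations of residual ranks between libraries of the same number ran from −0.193 to 0.416 (median 0.0734, 30 pairs), and those between different numbers from −0.343 to 0.348 (median −0.105, 60 pairs). For 10 of 15 libraries, the mean correlation with libraries of other groups was highest for their own number. Lists of the same number shared more bases (Jaccard index 0.713 against 0.697, difference 0.0165, one-sided permutation p = 0.0140). With the block, the globin sites past the threshold over the list alone numbered 2 for dCas9-KRAB with Cr10 against no gRNA and 1 for Cr4 against Cr10 by rank. On the summit pileup with the block they numbered 4 and 2 for dCas9-KRAB with Cr4 and with Cr10 against no gRNA, 3 for dCas9-KRAB against dCas9 with Cr4 and 1 for Cr4 against Cr10, and 3′ HS1 was −0.0202. HS2 was 1 of the 3 against dCas9 with Cr4 (log2 −0.35, limma adjusted p over the list alone 0.0405). It was also the 1 site for Cr4 against Cr10 (0.46, limma adjusted p over the list alone 0.00992). With the block on the pileup, limma called 1 region of 38888, which was HS2, in dCas9-KRAB with Cr10 against no gRNA (adjusted p 3.74e-05). The same 1 region was called against dCas9 with Cr10 (limma adjusted p 0.00929) and in the pooled comparison (8.80e-05).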

Other observations

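All tests in this part were chosen after the ranks had been seen, except the regroupings of libraries in the last paragraph. For those and for the local background at HS1, predictions were written before their values. The test of the local background was chosen to explain a difference already seen by rank.

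On the implied summit pileup, HS2 was lower with both gRNAs under dCas9-KRAB than without a gRNA, by −0.69 in log2 with Cr4 (0.620 times the pileup) and −1.15 with Cr10 (0.452 times), with limma adjusted p over the list alone of 0.00573 and 2.31e-05 and over all regions of 1.00 and 0.0999. Against dCas9 with the same gRNA it was lower with Cr10 by −0.86 (adjusted p over the list alone 0.00115), while the difference with Cr4 was −0.35 (0.168). HS3 was 0.570 times as high with dCas9-KRAB and Cr4 as without a gRNA (log2 −0.81, adjusted p over the list alone 0.00541) and 0.629 times with dCas9-KRAB and Cr10 (−0.67, 0.0155), while these comparisons share the 3 libraries without a gRNA. With dCas9 and no KRAB it differed by −0.24 with Cr4 and −0.41 with Cr10 (limma adjusted p over the list alone 0.631 and 0.489). Directly against dCas9 with the same gRNA, dCas9-KRAB differed at HS3 by −0.57 with Cr4 and −0.26 with Cr10 (0.0968 and 0.483), neither past the threshold, and by −0.42 over both gRNAs (0.0396). In the pooled comparison the HBG2 promoter was lower by −0.37 (SE 0.12, adjusted p over the list alone 0.0171), and HBG1 differed by −0.24 (0.0982). Against no gRNA, HBG2 and HBG1 differed under dCas9-KRAB by −0.55 and −0.51 with Cr4 (limma adjusted p over the list alone 0.0192 each) and by −0.33 and −0.25 with Cr10 (0.294 and 0.400). Cr4 against Cr10 gave −0.22 and −0.27 (0.742 and 0.64998), so a difference between the gRNAs was not shown. HS5, 3′ HS1 and the HBD promoter differed by −0.05, −0.02 and 0.03.

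A further 37 tested regions at gene starts and enhancers were taken from recalled hg19 positions, after the lists had arrived and before their values were seen. On the pileup limma called 0 of the 37 over that list alone in the pooled comparison, with 1 at an unadjusted p under 0.05, and the differences ran from −0.20 to 0.19. The alpha-globin enhancer HS-40 differed by 0.09, and the starts of HBA2, HBA1 and HBZ by 0.18, 0.13 and 0.09. HS-40 and the starts of GATA1, TAL1 and KLF1 had peaks in all 15 lists, and those of MS4A1, PAX5, ALB and BCL11A had peaks in 0 lists. At 2 loci that share sequence with parts commonly carried by such vectors, the 12 libraries with a gRNA were compared with the 3 without, by two-sided exact permutation adjusted over 6 tests. The log2 pileup was higher at the RNU6-1 start by 0.24 (adjusted p = 0.0462), and ZNF10 differed by 0.06 (adjusted p = 0.798). By rank the adjusted exact p was 0.0791 at RNU6-1 and 0.522 at ZNF10. This split follows the gRNA and not KRAB, which all 3 libraries without a gRNA had and 6 of the 12 lacked. The value at ZNF10 therefore cannot show reads from a vector part that goes with KRAB.

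The HS2 summit pileup was lower in the 6 libraries with dCas9-KRAB and a gRNA than in the other 9 by −0.71 (0.611 times, exact permutation p = 0.000799), and limma ranked it first of 38888 regions. Lower depth is argued against by the 1000 regions of nearest mean pileup, whose differences had a median of 0.00404 (SD 0.082, lowest −0.23). The count of 0 of them as low as HS2 adds nothing, since HS2 was the lowest of all regions. The centring on the median of each library had also removed overall depth beforehand. Binding of dCas9 alone as the whole cause is argued against by the difference between dCas9-KRAB and dCas9 over both gRNAs, −0.61 (SE 0.13, limma adjusted p over the list alone 0.00118), but a part of it stays open, with dCas9 and a gRNA at −0.31 (SE 0.16, adjusted p 0.370) from dCas9-KRAB without a gRNA. Chance is not excluded across the whole genome: 6 of 100 groupings, the real one among them, had a region with a t at least as large (real 5.79, highest other 7.79). Of the 5 others, 1 kept 5 of the 6 real libraries and had its largest t at HS3. The remaining 4 were uneven in replicate number, a share close to the 76 of all 99 others, so unevenness does not set them apart. Whether structure among the libraries contributed was not tested, also for the 319 regions that the grouping with the highest t called. The groupings and their t did not take the replicate number into account. With that number as a block, HS2 passed over all 38888 regions in the pooled comparison (limma adjusted p 8.80e-05). No regroupings were run with the block, so chance was not weighed for that fit.

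HS1 and HS4 ranked higher in the 6 libraries with dCas9-KRAB and a gRNA, although the rank depends on the local background as well as on the reads at the summit. The log2 local background was lower at HS1 by −0.34 (exact permutation p = 0.0190) and at HS4 by −0.15 (p = 0.420), so a lower background could have raised the rank of HS1, and the explanation remains open for the 2 sites together. The mean of the pileup differences at the 2 sites was 0.12, which leaves open whether the summits held more reads. The local background was also lower at HS2 by −0.39 (exact permutation p = 0.0164) and at HS3 by −0.30 (p = 0.0468). No biological explanation was tested for HS1 and HS4.

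HS3 and HBG2 were lower together with HS2, and fewer copies of the whole locus would lower all sites of the cluster. The mean pileup difference over HS1, HS4, HS5, 3′ HS1 and the HBD promoter was 0.0419 (SE 0.13), and HS3 lay −0.57 (SE 0.14) below these sites. HS3 was among the sites that prompted this test and the others were not, so part of that gap is built in. The SE does not cover this choice. With that limit, the mean over the other sites argues against a fall of the whole cluster as large as at HS3. Over the 10 regions of the cluster without HS2 the mean was −0.11, and 0.0698% of 38661 runs of as many neighbouring regions had a mean as low. That mean was carried by HS3, HBG2 and HBG1, the sites that prompted the test, so it decides nothing about chance, which stays open. No test separates spread of repression from HS2 from an indirect effect.

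By rank, the real groupings gave 0 regions past the limma threshold, a count that every grouping reaches by construction (10 of 10 in each comparison of 3 against 3 and 100 of 100 in the pooled one), so these shares say nothing about chance. The highest other counts were 0, 1, 7, 0, 0, 9 and 0 in the order dCas9-KRAB with Cr4, dCas9-KRAB with Cr10, dCas9 with Cr4 and dCas9 with Cr10 against no gRNA, dCas9-KRAB against dCas9 with Cr4 and with Cr10, and Cr4 against Cr10, and 2 in the pooled comparison. For regions gained or lost, the real counts of 187, 333, 58, 96, 192, 192 and 401 were reached by 9, 9, 10, 10, 9, 9 and 9 of 10 groupings, with highest other counts of 2206, 1576, 3341, 3630, 2592, 1991 and 1695. With 10 groupings no share can fall under 0.1. The pooled count of 0 was reached by 100 of 100, again by construction, with a highest other count of 14.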
